A study of Rattus norvegicus with 4 samples.

How the data were processed

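Total RNA of 4 cultures of the rat alveolar macrophage line NR8383 was measured, each on its own array. Per the labels, cells at passage 20 were seeded in 25 cm2 flasks for 48 h, carried 1 treatment label (TiO2 at 3 cm2/cm2), and gave RNA of an integrity number above 7.5. Cy3-labelled cRNA was made from 100 ng of RNA, per the labels' protocols. Group and replicate number came from the sample titles. With 1 group, no comparison between treatments was possible, and unexposed cells were not analysed here. All 4 arrays lay on 1 slide, per the file headers, so slide was no batch.

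The deposited intensity values are processed spot signals from Agilent Feature Extraction 11.0.1.1, background-subtracted and detrended across the array but not scaled between arrays, per the file headers. The tool and version are also named in the submitters' processing notes. The other deposited columns used here were the median spot and background signals, per the file headers, and flags for saturation, outlying spots and signal above background. Each array has 62976 spots, of which 58717 are not controls.

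Levels were log2 of the processed signal minus the array's 75th percentile over non-control spots, after spots flagged as non-uniform or population outliers were left out (634 to 669 per array). Spots of 1 probe were averaged, and 3 probes lost all their spots on an array. Of 45598 probes, 21109 were named through their accession, without versions, by the RefSeq gene table of assembly GRCr8, and 24489 were not named. The array's grid is annotated on an older rat build, so no coordinates are given. Where a gene had several probes (3658 of 16579 genes) the brightest represented it. A probe was detected where the flag for signal well above background was set on over 0.5 of its spots, and a gene where any of its probes was. For 591 genes 1 probe was detected on all arrays and another on none. A probe's level was not set against another probe's.

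The 22 gene lists, the rule for named genes and the tests below were fixed before the data were examined, except the tests said to have been added. The lists hold 386 symbols, of which 360 had a probe and 261 were detected on all 4 arrays. The text gives values for the first 3 measured members of each list, for the member with the largest SD among those detected on all 4 arrays, for the 10 genes with the largest SD among those called more variable, and for markers of other cell types detected on all 4 arrays. A few genes that this rule names are not reported here. List detection was compared with all other measured genes by Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over 22 lists, a test added after the data had been seen.

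Variation between the arrays, each with its own culture, was tested with limma 3.58.1 in R 4.3.3. Each gene's variance over the 4 arrays (3 degrees of freedom) was divided by a prior variance with a trend on level and robust estimation (24.3 prior degrees of freedom), and the upper tail of the F distribution was adjusted by the Benjamini-Hochberg method, with calls at 0.05. Tables were handled with the packages data.table (version 1.17.8), matrixStats (1.5.0) and jsonlite (2.0.0). For each list with at least 3 genes, the median SD and the median deviation per array were set against 10000 random lists matched in 20 bins of mean level. Dixon's ratio of gap to range was compared with its 95% critical value for 4 samples. The variance test was tested on simulated data: of 7570 simulated genes, it called 6% of those with an SD raised 2 times, 26% at 3 times, 58% at 4 times and 90% at 6 times, and 1 of 7370 unchanged genes. The simulated noise was independent and drawn from the fitted prior, without noise tied to array position. The prior degrees of freedom recovered from it were 14.0, against 24.3 used, so these rates may not hold for the real arrays. A list whose SD was raised 2 times came out at percentile 100, and 1 of 20 other lists lay at 95 or above.

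Alternatives were a normexp background correction (offset 50) on the median spot and background signals, in place of mean signals, which were not used here, quantile normalization, scaling to the median of detected probes, the mean over a gene's detected probes, other detection flags and filters on dim genes, other forms of the prior, 50 bins, flagged spots kept and each replicate left out. Scaling to the 75th percentile of detected probes, genes printed beyond column 72 alone and random lists matched also on columns 1 to 72 were added after seeing the data. The number of arrays limits the precision, as does spot noise. The median SD between single spots of 1 probe was 0.14 on replicate 1, 0.06 on replicates 2 and 3 and 0.08 on replicate 4. Between arrays it was 0.15 for the same 1010 probes, but there each value was a mean over the probe's spots. Spot noise is smaller in such a mean, so these SDs are not like quantities. Most probes (43279 of 45598) were printed on 1 spot and have no such averaging.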

Results

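NR8383 is a macrophage line established from the lung lavage of a normal rat. Its cells take up particles, and here they had been exposed for 4 h to a titanium dioxide material, NRCWE001, at 3 cm2 of particle surface per cm2. RNA of 4 cultures (replicates 1 to 4, described as biological replicates in the series' design text) was measured on 4 one-colour arrays. The design text also names unexposed cells, which were not analysed here, so no value below says whether a transcript was raised or lowered by the particles. The comparisons that remained were of each probe with its array's background, and of the 4 exposed cultures with each other. As each culture had its own array, differences between cultures and between arrays come together.

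Each array held 45598 distinct probes beside its controls. The 75th percentile of the processed signal was 480 intensity units on replicate 1, 388 on replicate 2, 614 on replicate 3 and 466 on replicate 4, over local backgrounds of 36 to 41 units. Between 15314 and 16708 probes per array were well above background, and no spot was saturated. Of 16579 genes with a symbol and a value, 7579 were detected on all 4 arrays (45.7%), 1004 on 1 to 3 arrays and 7996 on none.

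The exposed cells carried transcripts of most macrophage markers, while markers of lung epithelium were mostly not well above background. Of 21 measured macrophage markers, 17 were detected on all 4 arrays, against 45.7% of all genes (Fisher's exact test, two-sided, adjusted p = 0.0041 over 22 lists). Cd68, a lysosomal glycoprotein of macrophages, lay at a log2 signal of 4.62 ± 0.14 (SD, n = 4) relative to its array's 75th percentile, the scale of every level below, which holds for the brightest probe of a gene. Csf1r, the receptor for macrophage colony-stimulating factor, lay at -0.53 ± 0.09, and Mrc1, the mannose receptor, at -2.35 ± 0.29. Marco, a scavenger receptor for unopsonised particles, and Adgre1, Cd163 and Cd74 were not well above background on any array. Among 16 uptake receptors 12 were detected on all 4 arrays (exact adjusted p = 0.042, and 0.0684 with a more lenient detection flag). Cd36, a scavenger receptor, lay at 2.13 ± 0.47, while Msr1, another one, was not well above background.

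Of 14 measured epithelial markers, 1 was detected on all 4 arrays (Fisher's exact test, adjusted p = 0.011). It was Foxj1, a transcription factor of ciliated cells, at -2.87 ± 0.35. The surfactant genes Sftpc and Sftpb and the adhesion gene Epcam were not well above background. This call was lost with the lenient flag (5 members, adjusted p = 0.208), when 1 array sufficed (5 members, 0.317) and without replicate 1 (2 members, 0.0513). Lymphoid markers were detected in 3 of 13 cases, granulocyte and mast cell markers in 3 of 14 and markers of fibroblasts and endothelium in 3 of 15, with exact adjusted p between 0.0916 and 0.178. When 1 array sufficed, the granulocyte and mast cell markers fell below all genes instead of the epithelial ones (exact adjusted p = 0.0415). The detected lymphoid markers were Nkg7 (-1.20 ± 0.19), Lck (-3.06 ± 0.17) and Cd4 (-3.34 ± 0.36), the last also known from rat macrophages. The granulocyte markers were Camp (2.11 ± 0.19), S100a8 (-1.46 ± 0.30) and Retn (7.92 ± 0.25). Those of vessels were Vwf (2.79 ± 0.23), Pecam1 (0.23 ± 0.12) and Cdh5 (-4.11 ± 0.30). The detected probes of Vwf differed widely, as their mean lay 3.27 below the level given. Cd3d was detected on 3 arrays, and Cd3e, Elane and Col1a1 were not well above background on any.

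**Figure D1:**
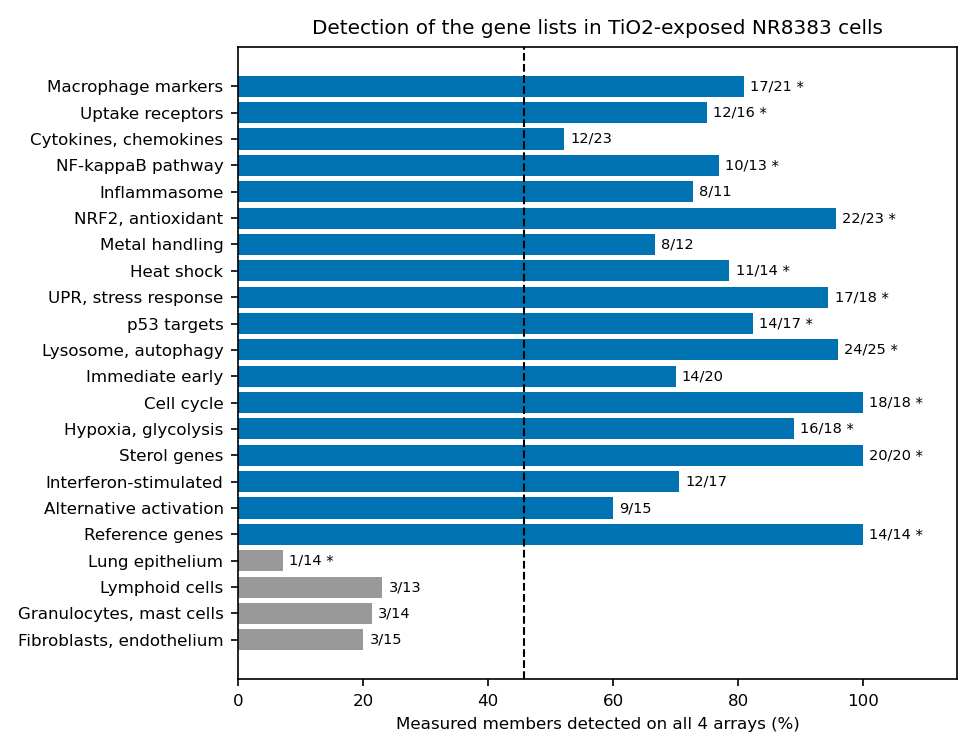
Share of the measured members of each gene list detected on all 4 arrays, in percent, with the counts beside each bar. The dashed line marks all genes (45.7%), grey bars are markers of other cell types, and an asterisk marks lists that differed from all other genes by Fisher's exact test after adjustment (12 above, 1 below).

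Antioxidant genes, many of them targets of the oxidative stress regulator NRF2, were detected almost completely, with 22 of 23 members on all 4 arrays (Fisher's exact test, adjusted p = 3.1e-06). Hmox1, the haem-degrading enzyme, lay at 5.69 ± 0.08 (SD, n = 4), so its 4 cultures differed little. Gclc, the catalytic subunit of glutathione synthesis, lay at 2.02 ± 0.10 and the quinone reductase gene Nqo1 at -1.37 ± 0.20. The ferritin gene Fth1 had the largest SD of the list (7.61 ± 0.36), and its many pseudogenes make its probe uncertain. The exception was Gclm, the other subunit gene of glutathione synthesis, which was not well above background. Among 12 genes of metal handling 8 were detected (exact adjusted p = 0.178). Of these, the metallothionein gene Mt1 lay at 3.23 ± 0.11, the zinc exporter gene Slc30a1 at 0.13 ± 0.07 and the transferrin receptor gene Tfrc at -0.46 ± 0.49, and Mt2A was not well above background.

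Transcripts of protein stress responses were present too. Genes of the unfolded protein and integrated stress responses were detected in 17 of 18 cases (Fisher's exact test, adjusted p = 6.34e-05). Atf4, the central transcription factor of the integrated stress response, lay at 4.97 ± 0.13, its target Ddit3 at 2.34 ± 0.24, Trib3 at 2.61 ± 0.32 and the chaperone gene Hspa5 at 3.17 ± 0.07. The kinase gene Ern1 was the member not well above background. Heat shock genes were detected in 11 of 14 cases (exact adjusted p = 0.0312, and 0.0508 without replicate 2). The inducible chaperone gene Hspa1a, which has near-identical copies, was not well above background, Hsph1 was detected on 3 arrays, and Hspb1 lay at -3.91 ± 0.30.

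Inflammatory transcripts were mixed. Of 23 measured members of the cytokine and chemokine list, 12 were detected on all 4 arrays, which did not differ from all genes (Fisher's exact test, adjusted p = 0.539). Tnf lay at 3.67 ± 0.18, Il1b at 3.65 ± 0.13 and Il1a at -0.05 ± 0.23, all 3 coding for early inflammatory cytokines. Il6, Il10, Il12b, Csf2, Ccl20 and Lif were not well above background on any array, nor were Nos2 and Ptgs2, enzyme genes that this list also holds. Of the NF-kB pathway 10 of 13 members were detected (exact adjusted p = 0.046, but 0.0695 with the lenient flag and 0.0652 to 0.0740 without replicate 1, 2 or 4). Nfkbia, the inhibitor that NF-kB itself induces, lay at 1.96 ± 0.28, Nfkb1 at 0.00 ± 0.14 and Nfkb2 at 1.42 ± 0.23. Inflammasome genes were detected in 8 of 11 cases (exact adjusted p = 0.154, and 0.023 when 1 array sufficed), with the adaptor gene Pycard at 0.58 ± 0.11, the sensor gene Nlrp3 at -0.49 ± 0.39 and the protease gene Casp1 at -2.99 ± 0.72. Interferon-stimulated genes were detected in 12 of 17 cases (exact adjusted p = 0.0738, and 0.023 when 1 array sufficed), with Mx2 at 2.14 ± 0.16 and Irf7 at -1.74 ± 0.50, while Mx1 was detected on 2 arrays. Alternative activation genes were detected in 9 of 15 (exact adjusted p = 0.322), with Tgfb1 at 2.11 ± 0.34 and Arg1 at -0.14 ± 0.20, while Retnla was not well above background.

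Genes of the lysosome, where ingested particles end up, were detected in 24 of 25 cases (Fisher's exact test, adjusted p = 1.73e-06). The cathepsin gene Ctsd lay at 7.71 ± 0.24, and the membrane protein genes Lamp1 and Lamp2 at 2.69 ± 0.06 and 2.70 ± 0.03. All 20 measured sterol genes were detected (exact adjusted p = 1.73e-06), among them Hmgcs1, an enzyme gene of the mevalonate pathway, at 0.76 ± 0.36. All 18 cell cycle genes were detected as well (exact adjusted p = 4.14e-06), with the cyclin genes Ccna2 at 1.34 ± 0.15 and Ccnb1 at 1.01 ± 0.06 and Mki67 at -0.86 ± 0.47. Of the p53 targets, 14 of 17 were detected (exact adjusted p = 0.00662), with the cell cycle inhibitor gene Cdkn1a at 3.51 ± 0.13, Gadd45a at -0.91 ± 0.27 and Mdm2 at -1.18 ± 0.53. Hypoxia and glycolysis genes were detected in 16 of 18 cases (exact adjusted p = 0.000616), with the glucose transporter gene Slc2a1 at 2.53 ± 0.16 and Hk2 at -1.60 ± 0.13, while Vegfa was not well above background. Immediate early genes were detected in 14 of 20 (exact adjusted p = 0.0644, but 0.0136 with the lenient flag and 0.023 when 1 array sufficed), with Fos at -3.12 ± 0.20, Egr1 at -3.63 ± 0.33 and Fosb at -3.95 ± 0.43. All 14 reference genes were detected (exact adjusted p = 6.34e-05). Of these Actb lay at 7.41 ± 0.15, Gapdh at 7.84 ± 0.27, Ppia at 7.57 ± 0.27 and Rplp0 at 7.46 ± 0.49, genes whose pseudogenes make their probes uncertain.

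**Figure D2:**
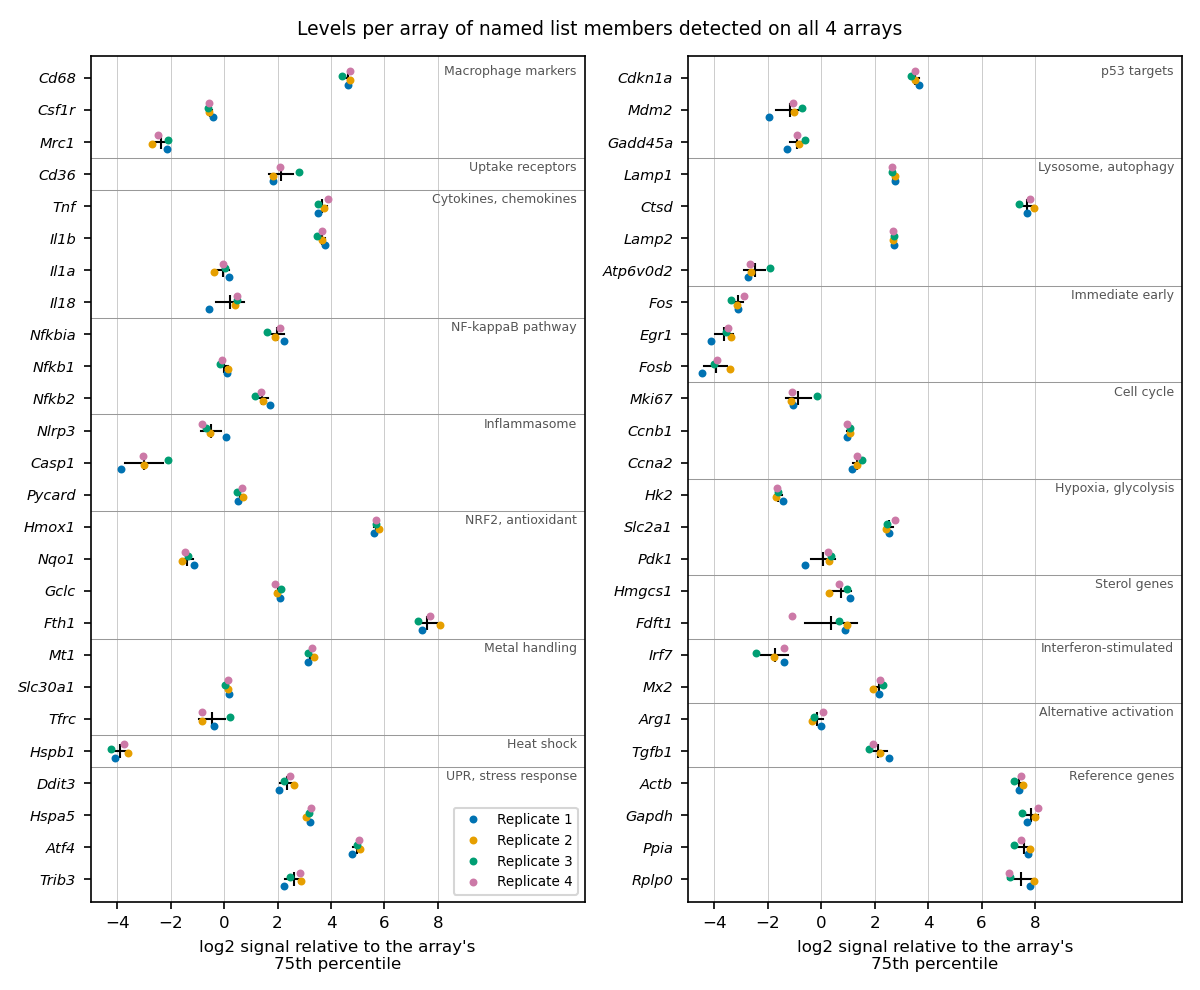
Log2 signal relative to the 75th percentile of each array for list members named by rule and detected on all 4 arrays, without those not reported here. Coloured points are the 4 replicates, vertical ticks their means and bars 1 SD (n = 4), and levels of different genes are not comparable because each probe responds differently. Hmox1 varied little (SD 0.08), while Il18 (SD 0.52) was low on replicate 1 and Fdft1 (SD 0.97) on replicate 4.

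Across 7570 genes whose probe was detected on all arrays, Pearson's r between pairs of arrays ran from 0.992 to 0.997. This r is over genes, which are not independent replicates and whose wide range of probe brightness alone brings r near 1. The median SD of a gene between arrays was 0.163 on the log2 scale, a fold of 1.12. None of 58717 non-control spots had exactly the same processed signal on any pair of arrays. A single array stood apart from the other three by Dixon's ratio in 413 genes (5.46%, where chance gives 5%), and replicate 3 was the low one in 139 of them. After scaling, replicate 3 had a median deviation of -0.08 over all detected genes, against 0.00 to 0.05 on the other arrays.

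Genes that varied between the arrays by more than genes of like level numbered 39 of 7570. They were called by limma's trended, robust prior variance at an adjusted p under 0.05. As each culture had its own array, the test cannot assign this spread to the cultures. An unadjusted p under 0.05 was found for 505 where chance gives 378.5. On simulated data the test called 6% of genes whose SD was raised 2 times and 26% at 3 times, so a gene not called is not shown to be stable. The largest SD belonged to Pcdh15, a protocadherin gene, which lay at -3.20 ± 1.14 and was farthest above its mean on replicate 2. Fdft1, squalene synthase, lay at 0.36 ± 0.97 and was 1.44 below its mean on replicate 4, where its probe lay in the last column (limma prior variance, adjusted p = 2.98e-05). Arnt2, a partner of the aryl hydrocarbon receptor family, lay at -1.73 ± 0.85 and was lowest on replicate 3. The other 7 genes of the 10 with the largest SD were all lowest on replicate 1. They were Cnot11 (-1.84 ± 0.97), Fbxo11 (-2.44 ± 0.92), Fam193b (-2.96 ± 0.81), Tox4 (0.92 ± 0.81), Lsm8 (0.64 ± 0.79), the motor neuron survival gene Smn1 (1.12 ± 0.78) and Mitf (-0.43 ± 0.77), a transcription factor of melanocytes and macrophage relatives. Without replicate 1, Mitf lay at -0.05 ± 0.04 and Lsm8 at 1.03 ± 0.07.

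Of the 39 genes, 30 were farthest from their mean as a low value on replicate 1, and all 30 had a spot at columns 1 to 72 of the array, where 47.4% of the tested genes had one (Fisher's exact test, two-sided, p = 1.73e-10). Those columns were chosen after the array had been looked at, so this p is smaller than a planned test would give. On that part of the replicate 1 array 5.18% of spots lay over 0.5 below their mean of the 4 arrays, against 0.417% beyond it, and 1.20% lay over 0.5 above it, against 0.232% beyond. The number of genes called also depended on the processing. With the median of detected probes as the scale 34 were called, after quantile normalization 0 (450 with an unadjusted p under 0.05 by limma's prior), and with normexp on median spot signals, which changes both signal and background correction, 208, while 32, 77, 10 and 16 were called without replicate 1, 2, 3 and 4.

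**Figure D3:**
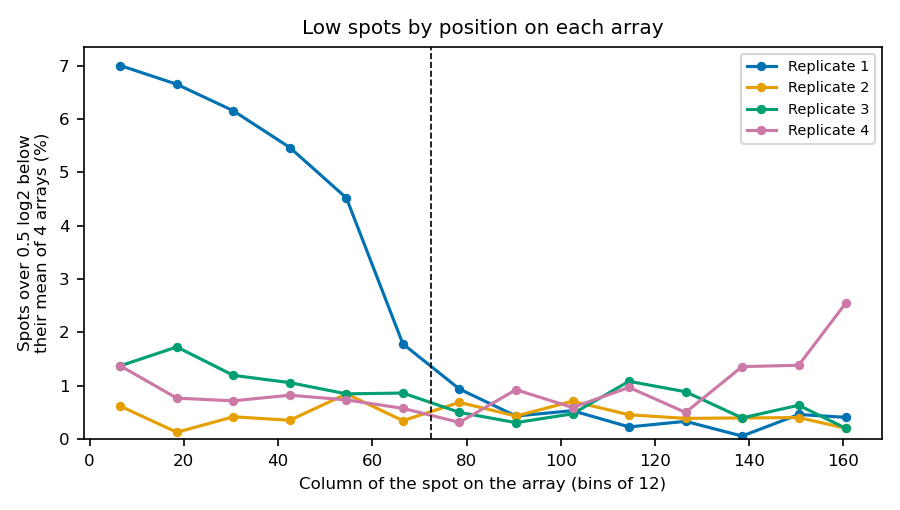
Percent of spots over 0.5 (log2) below their mean of the 4 arrays, by column on the array in bins of 12, for spots well above background on all arrays. Replicate 1 falls from 7.01% in the first bin to under 1% beyond column 72, marked by the dashed line, and the other replicates lie at 0.45% to 1.16% over columns 1 to 72, with replicate 4 at 2.55% in the last bin.

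Gene lists varied between the arrays to different degrees. The median SD of the 12 detected cytokine genes was 0.242, at percentile 99.97 of 10000 random lists matched on level, whose median was 0.151. The 8 inflammasome genes had a median SD of 0.369 (percentile 99.99), the 14 p53 targets 0.255 (percentile 99.88), the 22 antioxidant genes 0.211 (percentile 99.05) and the 12 interferon-stimulated genes 0.211 (percentile 97.83). Reference genes (0.202, percentile 95.74) and granulocyte markers (0.249, percentile 95.47, 3 genes) were also above the 95th percentile, so 7 of 21 lists were, as a description of these arrays. The 18 cell cycle genes, at 0.123, and the 17 macrophage markers, at 0.137, lay at percentiles 6.17 and 12.45. Without replicate 1 the inflammasome list fell to percentile 15.6 and the p53 list to 17.29, while the cytokine list lay at 97.8, and 3 lists in all were above the 95th. With normexp the inflammasome, p53 and antioxidant lists fell to 90.33, 88.67 and 73.47, and beyond column 72 the p53 list to 83.34. The p53 list lay at 92.73 without replicate 3, the antioxidant list at 94.23 and 87.9 without replicate 1 and 4, and the interferon list at 92.29 and 93.15 without replicate 1 and 3, 93.56 without a filter and 88.68 beyond column 72. The reference genes fell to 76.23 (beyond column 72) and the granulocyte markers to 61.62 (without replicate 3) at the lowest. In the inflammasome list Il18 had the only adjusted p under 0.05 (0.0297 by limma's prior variance over all genes), and 4 members passed when adjusted over the list alone. Il18 also stands on the cytokine list, where it was again the only call over all genes, beside 3 adjusted over the list alone. Of the p53 targets, Bbc3, an apoptosis gene named here after its values were seen, passed over all genes, and 4 did adjusted over the list alone. Bbc3 lay 0.69 below its mean on replicate 1, with a spot at column 15. Its SD was 0.48 on all arrays and 0.19 without replicate 1. Il18 lay at 0.20 ± 0.52 on all arrays and at 0.46 ± 0.05 without replicate 1.

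**Figure D4:**
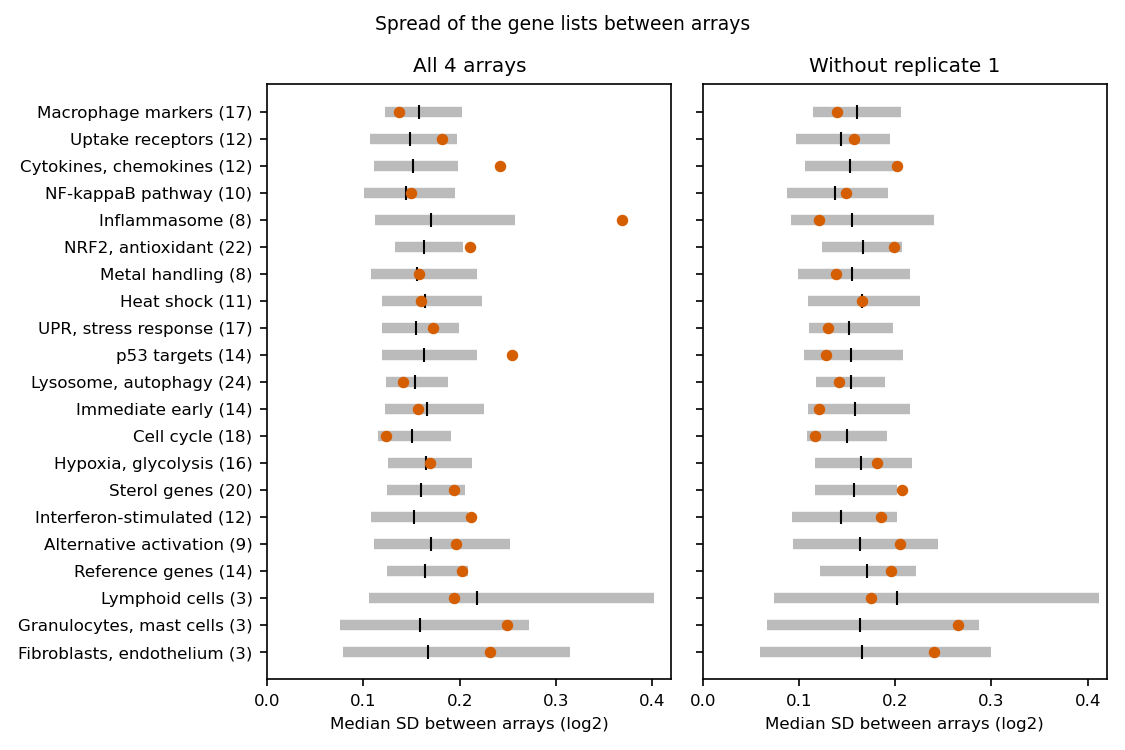
Median SD between arrays (log2) of each gene list with at least 3 detected genes (number in brackets), on all 4 arrays and without replicate 1. Orange points are the lists, and grey bars and ticks are the central 95% and the median of 10000 random lists matched on level. The inflammasome list (0.369 on all arrays) lies outside the random range only on the left.

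Some lists lay apart from random lists on single arrays. Replicate 3 had a median deviation of -0.08 over all detected genes. A list above random lists there need not lie above its own mean. The cytokine list lay 0.15 below random lists of like level on replicate 1 (percentile 0.04, 9 of 12 genes below their mean), and 0.12 and 0.11 above them on replicates 2 and 4 (percentiles 99.99 and 99.92). Deviations are from the mean of the arrays, and without replicate 1 the shifts on replicates 2 and 4 were 0.01 and 0.04 (percentiles 60.63 and 88.8), neither outside the random range. On replicate 2 the shift was also lost with normexp (0.05) and without a filter (0.06), and on replicate 4 beyond column 72 (-0.0179). Genes of the integrated stress and unfolded protein responses lay 0.14 below on replicate 1 (percentile 0.06, 11 of 17 genes below their mean). Interferon-stimulated genes lay 0.13 above on replicate 1 (percentile 99.35) and 0.11 above on replicate 4 (percentile 99.47). The first was lost without a filter (0.02) and without replicate 3 (0.06), and the second with normexp (0.05), the mean over probes (0.06), without replicate 2 (0.08) and beyond column 72 (0.10). The inflammasome list lay 0.20 above on replicate 3 (percentile 98.37, 5 of 8 genes above their mean), where Casp1 was 0.91 above its mean. This was lost with normexp (0.08), the mean over probes (0.16), other filters (0.12 and 0.16) and without replicate 1 (0.07) or 2 (0.08). On replicate 3 the cell cycle list lay 0.11 above random lists (percentile 99.51). Its own median deviation there was -0.00046, with 9 of 18 genes above their mean. The difference from random lists was lost after quantile normalization (0.07), with the mean over probes (0.07), without replicate 4 (0.06) and beyond column 72 (0.04). Of 84 combinations of list and array, 20 lay outside the central 95% of random lists, where lists of unrelated genes give about 5%. When only genes printed beyond column 72 were used, a setting chosen after seeing the data, 8 of 60 did. Without replicate 1, 2, 3 and 4, 11, 10, 12 and 13 of 63 did. These combinations are not independent, as a gene's deviations are from its own mean and some genes stand on several lists. Genes of 1 list can also vary together, which random lists do not reproduce, so the excess over 5% is a description only.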

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

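The columns studied on replicate 1 were chosen after its array had been looked at, as were the tests that use them; the test of other probes of the called genes was written after its values had been seen, and the lists matched on array position were added. Of 73 named genes detected on all 4 arrays, 8 had 1 array far from the other three, where chance gives 3.65 and where the named genes include some picked for a large SD. On replicate 1 the low genes were Mitf (gap over range 0.948, 1.16 below its mean), Il18 (0.915), Fam193b (0.914), Lsm8 (0.912) and Pdk1 (0.881), a kinase gene of glucose metabolism. Replicate 3 was high for the proliferation marker Mki67 (0.905) and for Atp6v0d2 (0.871), a subunit of the lysosomal proton pump. Replicate 4 was low for Fdft1 (0.859), whose probe sits in the last column of the array, as does that of Bpifb2 (1.11 below its mean there, named after its values were seen); replicate 4 had 2.55% of spots over 0.5 below their mean of the arrays in its last bin of columns. Another 5282 probes without a gene symbol were well above background on all 4 arrays and entered no gene comparison.

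Most genes called more variable were lowest on replicate 1 (30 of 39). For probes printed on 10 spots, spots lying over 0.5 below their own probe's median on the same array were 6.17 percentage points more frequent at columns 1 to 72 than beyond on replicate 1, against 0.083, 0.19 and -0.064 on replicates 2, 3 and 4. Spots over 0.5 above it were more frequent there too (1.58% against 0.586%). The spread of spots about their probe's median was 0.184 there, against 0.082 beyond. This spread is a median absolute deviation, scaled to equal an SD for normal noise. Per bin of columns, the median deviation from the mean of the 4 arrays ran from 0.038 to 0.056 there, and from -0.025 to 0.021 beyond. In the processed signal, which was already detrended across the array, the zone was thus noisier, with more low spots, but not dimmer as a whole. Low spots are a candidate cause of these calls. All 30 genes had a spot in the zone, against 47.4% of the tested genes. A fall of transcripts in culture 1 would not follow the columns of the array. For the 30 genes as a set, this argues against such falls as the source of most calls, though the columns were chosen after the array had been looked at. Another probe was detected for 5 genes (Aldh18a1, Arl6ip1, Miip, Mitf and Srebf1). Those probes deviated by a median of -0.0154, against -0.73 to -1.16 for the called ones. The other probes outside the zone all lay below their mean, by 0.02 (Arl6ip1), 0.17 (Mitf) and 0.28 (Miip). Those in the zone lay above it, by 0.35 (Aldh18a1) and 0.04 (Srebf1). These values argue against a fall of the called probes' size in the transcripts of these genes. A smaller fall stays open in these genes. The other probes of Aldh18a1 and Srebf1 lie in the zone too, and r between probes of a gene was 0.147 on replicate 1. For any single gene of the other 25, with no second detected probe, a fall of any size stays open.

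The cytokine list lay below random lists on replicate 1. General noise at columns 1 to 72 was argued against, as the list stayed at percentile 0.02 among random lists matched on that position. A difference between arrays that depends on brightness would shift random lists of like level alike. The percentile of 0.04 among these thus argues against it. After quantile normalization the percentile was 0.06, which adds little, as the random lists were matched on level there too. The 6 members printed beyond column 72 had a median deviation of -0.15, and 4 of 6 lay below their mean. Their deviations were split, from -0.27 to 0.22. The standard error of 0.08 is over these genes, which are not replicates. The median is at percentile 1.36 among random lists beyond column 72, a value against a dim zone as the whole cause. The bound of -0.1 set for excluding it was not passed by more than the standard error, so this test cannot decide. The zone's median deviations per bin on replicate 1 (0.038 to 0.056) argue against a zone dim as a whole in the processed signal. That signal was already detrended across the array, so they do not tell whether the zone was dim before this step. Low values at the spots of single members and a difference of the culture cannot be told apart. No biological explanation was tested, as the design gives the cultures no second factor.

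The inflammasome and p53 lists varied more than random lists (percentiles 99.99 and 99.88, but 90.33 and 88.67 with normexp). Both fell without replicate 1, to percentiles 15.6 and 17.29. Leaving out an array takes away a fault of that array and a difference of its culture alike. A fault at columns 1 to 72 and a difference of culture 1 thus cannot be told apart by this step. Matched on position, the lists lay at percentiles 99.9 and 99.8, which argues against the ordinary noise of columns 1 to 72 as the whole cause. Of their members 7 of 8 and 9 of 14 have a spot at columns 1 to 72 (47.4% of tested genes do), among them Il18, Nlrp3 and Casp1, and they went both ways on replicate 1, with 5 of 8 inflammasome genes and 6 of 14 p53 targets below their mean (Il18 by 0.78, while Nlrp3 lay 0.56 above), and the inflammasome list's largest shift was on replicate 3 (0.20 above, percentile 98.37), without which its spread lay at 99.96. What stays open is a fault at these particular spots or a difference of culture 1. For the inflammasome list, percentiles of 99.96 without replicate 3 and 15.6 without replicate 1 argue against culture 3 as the main source of its spread. Without replicate 1 the shift of this list on replicate 3 was 0.07 (percentile 82.32), inside the random range. The p53 list also fell without replicate 3, though less than without replicate 1, so a part played by culture 3 stays open there.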

How the results depend on the processing

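No paired analysis was possible because all samples belong to 1 group. Alternatives using column 72 or the 75th percentile of detected probes, and the tests of list detection, were added after the data were seen. Signal over background limits all levels, as 7996 of 16579 genes were not well above it on any array. Counts of detected genes (7579 to 9160) and of detected list members (261 to 287) stayed within 1.5 times under every alternative run, as did the share of genes with 1 array apart (4.22% to 6.05%), which was not run with 3 arrays because Dixon's ratio was set for 4. The number of genes called more variable was the least stable: 39 in the report, 208 with normexp, 0 after quantile normalization (450 at an unadjusted p under 0.05 by limma's prior), 0 with the 75th percentile of detected probes (403), 0 without the trend of the prior (467), 9 without robust estimation, 127 without a filter on dim genes, 5 beyond column 72 (fewer genes tested), 17 at an adjusted p under 0.01, and 10 to 77 with 1 replicate left out (32 without replicate 1, of which 8 were shared; 77 without replicate 2; 10 without replicate 3; 16 without replicate 4). Of the 39, 38 were also called with normexp. The cause was not tested except where named. The median level of the named genes, 0.23, was 2.86 after quantile normalization, 0.79 with the median of detected probes and -1.49 with their 75th percentile, because these settings move the zero of the scale. Of the 73 named genes detected on all 4 arrays, single levels moved by more than their SD in 35 with normexp (at most 1.72, Cdh5), in 12 with the mean over probes (at most 3.27, Vwf, from 2.79 to -0.49, with Tnf from 3.67 to 0.89 and Cdkn1a from 3.51 to 0.46), in 20 with outlying spots kept (median change -0.16, at most 0.23) and in 0 with a replicate left out. The probes of Vwf, Tnf and Cdkn1a thus differed widely in signal, which the SD of a level does not show. The lowest correlation was 0.987 for genes detected on at least 1 array and 0.990 without a filter, settings that add dimmer genes, and the median SD was 0.274 without a filter and 0.136 to 0.172 with 1 replicate left out (0.136 without replicate 3).

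Lists above percentile 95 for spread numbered 7, against 2 beyond column 72 (of 15 lists, not 21) and 3 to 6 with 1 replicate left out (3 without replicate 1); with 1 replicate left out, the inflammasome list ran from percentile 15.6 (without replicate 1) to 99.96 and the p53 list from 17.29 (without replicate 1) to 99.98. List shifts outside the central 95% numbered 20 of 84, against 13 of 88 without a filter, 8 of 60 beyond column 72 and, of 63, 11, 10, 12 and 13 without replicate 1, 2, 3 and 4. Beyond column 72 the shift of the cytokine list on replicate 4 turned to -0.0179, and that of the sterol list on replicate 3 to -0.0131; the cause was not tested. Lists detected less often than all genes numbered 1, but 0 with the lenient flag, 1 when 1 array sufficed (granulocyte markers, 0.0415, in place of epithelial ones, 0.317) and 0 to 1 with 1 replicate left out (0 without replicate 1), by Fisher's exact test.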

Other observations

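The correlation between probes of a gene was chosen after the data had been seen. Among list shifts not yet described, uptake receptors lay 0.10 above random lists on replicate 3 (percentile 97.63, 6 of 12 genes above their mean). On replicate 4 they lay 0.11 below (0.93, 4 of 12 genes above their mean). Hypoxia and glycolysis genes lay 0.10 above on replicate 4 (percentile 99.68, 14 of 16 genes above their mean). NF-kB genes lay 0.10 below on replicate 3 (0.79, 9 of 10 below or at their mean). Sterol genes lay 0.11 above random lists on replicate 3 (99.24, 11 of 20 genes above their mean). Smaller shifts were those of antioxidant genes (0.08 above random lists on replicate 3, percentile 98.55, and 0.09 below on replicate 4, 0.5). On replicate 3 the antioxidant genes' own median deviation was -0.06, with 6 of 22 above their mean. Stress response genes lay 0.06 above on replicate 2 (97.91), reference genes 0.06 above on replicate 2 (98.36) and sterol genes 0.08 below on replicate 4 (2.46). Few-gene shifts were those of 3 genes each of granulocytes (0.16 below on replicate 3, 1.87) and vessels (0.18 above on replicate 2, 97.65). Each of these shifts lay inside the central 95% under at least 1 alternative, such as those of uptake receptors without replicate 2 (0.06 and -0.09), of hypoxia genes with the mean over probes (0.06), of NF-kB genes without replicate 1 (-0.06) and of sterol genes with normexp (0.05 and -0.04), and all others without replicate 1 except the antioxidant one on replicate 4, lost without replicate 2 (-0.05). With 84 combinations of list and array, which are not independent, about 5% would lie outside the central 95% for lists of unrelated genes.

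Across 1339 genes with at least 2 detected probes, Pearson's r between the deviations of the 2 brightest was 0.38, and by array 0.147, 0.405, 0.585 and 0.318 for replicates 1 to 4, over genes, which are not independent replicates.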
